A study of Saccharomyces cerevisiae with 34 samples.

How the data were processed

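The samples were 34 sequencing libraries from Saccharomyces cerevisiae of the SK1 background grown in rich medium, and each was either an mRNA-seq library or a ribosome profiling library, in which the mRNA fragments protected by ribosomes (footprints) are sequenced. They belong to a pair of experiments on the unfolded protein response, the transcriptional program that follows accumulation of misfolded protein in the endoplasmic reticulum (ER), and on Hac1, the transcription factor of that response. In the deletion experiment, cultures of a wild-type (WT) strain and of a strain with HAC1 deleted were each split into 3 subcultures, left untreated, given 5 mM dithiothreitol (DTT, which reduces disulfide bonds) or given 2 µg/mL Tm (tunicamycin, which blocks N-glycosylation), per the labels' protocols. Each strain and treatment has 1 mRNA library and 1 footprint library, 12 in all. In the auxin experiment, a strain without and a strain with TIR (the plant F-box protein through which auxin triggers degradation of tagged proteins) received 500 µM auxin with 4 µM IP6, or vehicle, and after 15 min 5 mM DTT or nothing more. The series design text says that these cells were wild-type or depleted for Hac1, so auxin-treated TIR cells are called depleted and auxin-treated no-TIR cells retained. The labels themselves do not describe the degradation tag. The libraries were taken at 1 h and 2 h, 22 in all. No-TIR cells with auxin alone have only the 1 h library of each molecule, and a 2 h library of that group was not analysed here.

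Groups were taken from the library titles. For the 12 deletion libraries another label field gives ribosome footprints for all, including those titled as mRNA. The titles and the column names were followed. The replicate number of the auxin experiment is the labelled hour. Nothing in the labels says that the 1 h and 2 h libraries of a group came from separate cultures, so every p-value measures the spread between these 2 time points around their shared difference, which may be technical.

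The authors deposited 2 tables of 6679 genes, 1 for each experiment. The deletion table holds RPKM (reads per kilobase, scaled to library size), per the file headers. The auxin table names no unit, and its deposited values were taken as RPKM because they have the same range, sums and gene set. CASAVA, bcl2fastq 2.17 and Bowtie2 are named without a role in the submitters' processing notes, and the aligner settings, genome build, annotation and counting rule are not given in the sources used here. Multiplied by coding length and summed, the values of a library come to between 3.36 and 3.73 M, so their denominator was smaller than all reads assigned to genes and is not stated. Within a library, 87.7% to 88.4% of values were whole multiples (within 0.02) of what 1 read is worth when the coding length is shortened by 60 nt. From that step the reads in genes were estimated, in M (mega) reads, at 10.2 to 32.4 M for auxin mRNA, 6.5 to 36.5 M for auxin footprint, 16.0 to 19.0 M for deletion mRNA and 8.4 to 27.4 M for deletion footprint libraries. These estimates describe depth only, and no count model was fitted. No column was left out. Of the identifiers, 5994 matched NCBI's RefSeq table of assembly R64, which was used for symbols and neighbouring genes alone, and 685 did not match and are named by their systematic name. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and near-identical copies such as RPL41A and RPL41B may share reads.

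All changes are on the scale of log2(RPKM + 1), which understates the change of genes with low values. In the auxin experiment, genes with a mean of at least 5 RPKM over the 11 libraries of a molecule were tested with limma's moderated test with a mean-variance trend (limma 3.58.1, R 4.3.3) in a model with a term for each group and an additive term for the hour, which left 4 residual degrees of freedom. All groups entered 1 model so that they share an estimate of spread. Translational efficiency (TE) was the log2 footprint value minus the log2 mRNA value of the matching libraries, fitted with the same design, in place of an interaction in a count model. Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called (said to rise, fall or change) at adjusted p under 0.05. Values are given as log2 change ± standard error, with 2 libraries per group except 1 for no-TIR cells with auxin alone, so the response with Hac1 retained rests on a single control library that is assumed to vary like the others. In all 7 contrasts were tested. The 29 gene lists, fixed before the data were examined, were ER protein folding, ER-associated degradation, ER translocation and signal recognition, N- and O-glycosylation, GPI anchor synthesis, ER-Golgi transport, phospholipid and fatty acid synthesis, ergosterol synthesis, the electron transport chain, respiratory chain assembly and coenzyme Q, ATP synthase, the TCA cycle, the mitochondrial ribosome, cytosolic ribosomal proteins, ribosome biogenesis, general stress (Msn2/4) genes, cytosolic heat shock (Hsf1) genes, redox (Yap1) genes, cell wall integrity genes, sulfur amino acid genes, amino acid synthesis (Gcn4) genes, the iron regulon, drug efflux (Pdr1) genes, the proteasome, glycolysis, meiotic genes, mating genes, UPR signalling (HAC1, IRE1 and TRL1) and a pair of examples the study itself chose, HNT1 and ODC2. Lists were compared with all other genes by camera (limma) with a preset correlation of 0.01 between genes, and again with an estimated correlation.

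The deletion experiment has 1 library per group, so no test was run and its differences have no replicate check. Genes were counted that changed at least 2-fold in the same direction under both drugs against the strain's own untreated library, among genes with RPKM of at least 10 in 1 library of the strain. For a fall in TE the rule was mRNA at least 1.5-fold higher and TE at least 1.5-fold lower under both drugs, with mRNA RPKM of at least 10 in every library. Both drugs share 1 untreated library. Counts were therefore set beside 100 simulations of unchanged libraries, drawn with the residual spread of the auxin experiment on the log2 scale. List medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins.

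Genes are named by a rule also fixed before the data were examined: HAC1, IRE1, KAR2, PDI1, HNT1 and ODC2 always; the 10 largest rises and 10 largest falls of mRNA with Hac1 retained, and of mRNA and of footprints on depletion, with mean RPKM of at least 10 and the same sign at 1 h and 2 h; 5 and 5 for each TE comparison; the 10 largest TE falls among genes with mRNA up and TE down; the 10 risers and 10 fallers of WT mRNA in the deletion experiment by the smaller change of the drugs; and up to 4 members of each list with the smallest p on depletion. Genes outside it were chosen after their values were seen and are said to be so.

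The tests were tried on simulated data with 200 changed genes and independent normal noise of the fitted spread. Such noise cannot show the error rate if the 1 h and 2 h libraries of a group came from 1 culture. For mRNA with Hac1 retained (5757 genes) the test recovered 85 of 100 genes changed by log2 1 and 95 of 100 changed by log2 2. Of its calls 5.8% were false. For mRNA on depletion the recovery was 96 and 99 with 5.3% false, for footprints with Hac1 retained (5338 genes) 89 and 100 with 4.5% false, for footprints on depletion 94 and 100 with 6.3% false, for TE with Hac1 retained (5329 genes) 91 and 98 with 2.1% false, and for TE on depletion 96 and 100 with 3% false. The alternatives were pseudocounts of 0.5 and 5, a mean of at least 20 RPKM, no filter, median-ratio scaling of the libraries, a model without the hour, only the groups compared, each library left out in turn, other folds and minimum RPKM values, and other list tests. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.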

Results

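mRNA abundance and ribosome occupancy were measured in parallel in yeast under ER stress, with Hac1 present, deleted or depleted, over 34 libraries. The deletion experiment has 12 libraries, 1 for each strain, treatment and molecule, and the auxin experiment has 22, with 2 (1 h and 2 h) for each group and molecule except 1 for no-TIR cells with auxin alone. Values are RPKM as deposited, and changes are log2 ratios of RPKM + 1.

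HAC1 (YFL031W, chromosome VI), the gene targeted in both experiments, was examined first in every library. In the deletion experiment HAC1 mRNA in WT cells was 2372.2 RPKM untreated, 5215.6 with DTT and 4324.8 with Tm, against 42.1, 5.4 and 17.7 RPKM in hac1 deletion cells. HAC1 footprints in WT were 178.5, 6242.9 and 4405.4 RPKM in the same order, against 54.4, 5.2 and 66.6 RPKM in the deletion. A reading frame that overlaps HAC1, YFL032W, was lower with it. In the auxin experiment, where the protein and not the gene is the target, HAC1 mRNA was 6192.5 RPKM in no-TIR cells with auxin alone, 5829.1 and 6222.4 RPKM in TIR cells with auxin alone, and 22574.4 to 29191.4 RPKM in the 8 libraries with DTT. HAC1 footprints were 380.0 RPKM, 456.6 and 567.5 RPKM, and 4380.7 to 5846.0 RPKM in those groups. HAC1 mRNA did not differ at the threshold between depleted and retained cells under DTT (−0.19 ± 0.13, limma adjusted p = 0.369), and neither did its footprints (−0.28 ± 0.12, adjusted p = 0.191). These mRNA values therefore check the labels of the deletion mRNA libraries and not the depletion of the protein.

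**Figure D1:**
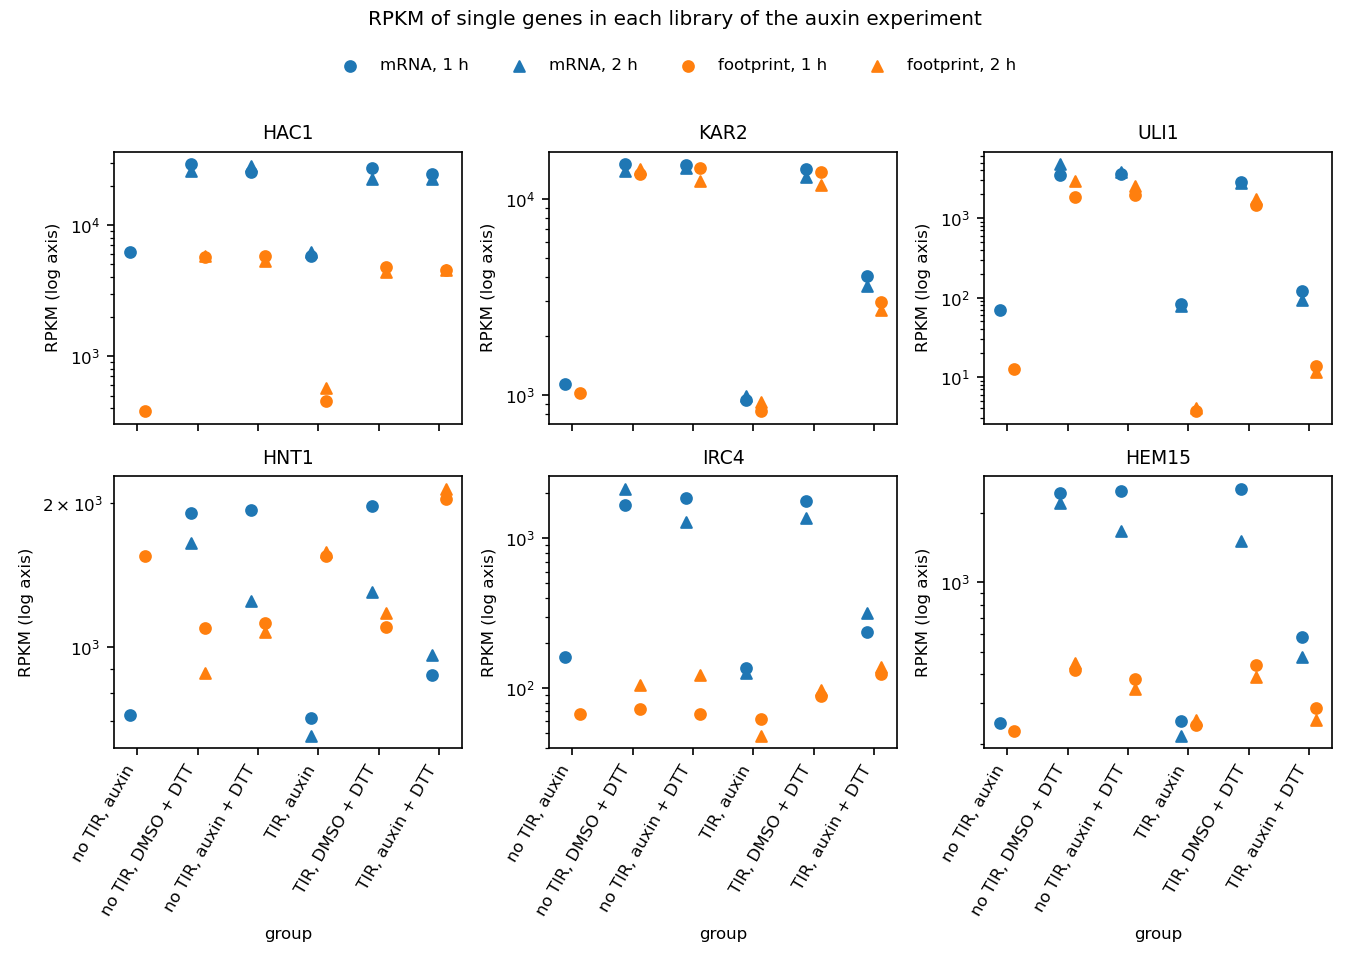
RPKM (log axis) of HAC1, KAR2, ULI1, HNT1, IRC4 and HEM15 in each of the 22 auxin libraries, with mRNA in blue, footprints in orange, circles for 1 h and triangles for 2 h. KAR2 mRNA was 14791 and 14385 RPKM in no-TIR cells with auxin and DTT and 4051 and 3595 RPKM in TIR cells with auxin and DTT.

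The response to DTT with Hac1 retained was measured in no-TIR cells, with auxin and DTT against auxin alone. Most ER chaperones and oxidoreductases rose, with many genes of ER-associated degradation, glycosylation and vesicle transport. Most genes of the respiratory chain, cytosolic ribosome and amino acid synthesis fell. KAR2 (YJL034W), the ER Hsp70 chaperone, rose by 3.71 ± 0.15 (limma adjusted p = 4.35e-08), from 1142 RPKM to 14791 and 14385 RPKM. PDI1, the protein disulfide isomerase, rose by 2.92 ± 0.18 (adjusted p = 7.88e-07), and ULI1, a gene of unknown function induced by ER stress, by 5.72 ± 0.23 (adjusted p = 3.64e-08). RTA1, of a family of membrane proteins linked to lipid export, rose by 6.84 ± 0.29, YET2, a homolog of an ER membrane protein, by 5.56. AAD6, a putative aryl-alcohol dehydrogenase, rose by 5.53 and FRE7, a putative metal reductase, by 4.56. Among the largest falls were ARG3 and ARG1 of arginine synthesis (−3.91 ± 0.18, adjusted p = 1.09e-07, and −3.34), YHB1, a flavohemoglobin (−3.37), and COX26 of cytochrome c oxidase (−3.02). Of 5757 genes tested 2338 were called, 1647 higher and 691 lower. Median-ratio scaling moved the median of all genes from 0.24 to −0.01 and the calls to 935 higher and 1063 lower, so list medians below are to be read against 0.24. The camera test compares each list with the other genes and is little affected by such a shift.

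Among the ER lists, 15 of 16 genes of ER protein folding rose and 0 fell (15 adjusted over the list alone). The folding genes had a median of 2.14, or 1.88 after median-ratio scaling (camera adjusted p = 1.15e-09, adjusted p = 0.0628 with an estimated correlation). ERO1, the oxidase that feeds PDI1, rose by 3.58 ± 0.17, and SIL1 and JEM1, cofactors of KAR2, by 3.41 and 2.81. In ER-associated degradation, 12 of 18 rose (15 adjusted over the list alone), or 9 after median-ratio scaling, among them DFM1 and DER1 of the membrane channel (2.69 and 2.43). The degradation genes had a median of 0.93 (camera adjusted p = 8.22e-05, adjusted p = 0.144 with an estimated correlation). In N- and O-glycosylation, 22 of 36 rose (25 adjusted over the list alone). Glycosylation genes had a median of 0.60, with PMT3, an O-mannosyltransferase, at 2.86 (camera adjusted p = 2.47e-05, adjusted p = 0.226 with an estimated correlation). In ER-Golgi transport, 22 of 29 rose (24 adjusted over the list alone), or 14 after median-ratio scaling. Transport genes had a median of 0.78, with the cargo receptors ERV29 and ERP2 at 1.69 and 1.52 (camera adjusted p = 8.47e-05, adjusted p = 0.144 with an estimated correlation). In GPI anchor synthesis, 12 of 22 rose (13 adjusted over the list alone), or 4 after median-ratio scaling. The anchor genes had a median of 0.64, with MCD4, an ethanolamine phosphate transferase, at 3.79 (camera adjusted p = 0.00238, adjusted p = 0.313 with an estimated correlation). ER translocation and signal recognition had 9 of 24 that rose (9 adjusted over the list alone) and a median of 0.29, or 0.04 with 8 rising and 1 falling after median-ratio scaling, and was not called as a list (camera adjusted p = 0.166).

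In the mitochondrial and ribosomal lists, 25 of 26 genes of the electron transport chain fell (25 adjusted over the list alone). The chain had a median of −1.57, with the cytochrome c1 gene CYT1 at −1.98 (camera adjusted p = 2.12e-20, adjusted p = 0.226 with an estimated correlation). All 14 ATP synthase genes fell (14 adjusted over the list alone). ATP synthase had a median of −1.10 (camera adjusted p = 1.93e-10, adjusted p = 0.226 with an estimated correlation). Of 11 TCA cycle genes 6 fell and 1, LSC2 of succinyl-CoA ligase, rose by 1.90, with 7 and 1 adjusted over the list alone and a median of −0.67 (camera adjusted p = 0.000272, adjusted p = 0.450 with an estimated correlation). For the mitochondrial ribosome 39 of 67 fell and 1 rose (49 and 1 adjusted over the list alone), or 58 and 1 after median-ratio scaling. The mitochondrial ribosome had a median of −0.63 (camera adjusted p = 1.59e-17, adjusted p = 0.330 with an estimated correlation). Respiratory chain assembly and coenzyme Q was mixed, with 9 of 34 falling and 6 rising (9 and 6 adjusted over the list alone), or 12 and 3 after median-ratio scaling, and a median of −0.19 (camera adjusted p = 0.0301, adjusted p = 0.603 with an estimated correlation). Of 138 cytosolic ribosomal protein genes 131 fell (133 adjusted over the list alone). Ribosomal proteins had a median of −0.82, with RPL18B at −1.33 (camera adjusted p = 2.96e-45, adjusted p = 0.0628 with an estimated correlation). Of 56 ribosome biogenesis genes 12 fell (3 adjusted over the list alone), or 31 after median-ratio scaling. Biogenesis genes had a median of −0.36 (camera adjusted p = 1.67e-09, adjusted p = 0.450 with an estimated correlation). Among amino acid synthesis (Gcn4) genes 26 of 27 fell (26 adjusted over the list alone), with a median of −1.16 (camera adjusted p = 3.56e-20, adjusted p = 0.0824 with an estimated correlation).

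Of the stress lists, cell wall integrity genes had a median of 1.24, with 14 of 19 rising and 1 falling (15 and 2 adjusted over the list alone; camera adjusted p = 0.00195, adjusted p = 0.518 with an estimated correlation). Drug efflux (Pdr1) genes had a median of 1.33, with 9 of 13 rising and 1 falling (9 and 1 adjusted over the list alone), and PDR5, an ABC exporter, rose by 1.05 (camera adjusted p = 0.00302, adjusted p = 0.384 with an estimated correlation). For the iron regulon 12 of 18 rose and 2 fell (12 and 2 adjusted over the list alone), or 8 and 3 after median-ratio scaling. The regulon had a median of 0.84 (camera adjusted p = 0.0209, adjusted p = 0.518 with an estimated correlation). For redox (Yap1) genes 11 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), or 8 and 1 after median-ratio scaling, with a median of 0.70 (camera adjusted p = 0.00761, adjusted p = 0.336 with an estimated correlation). Of the proteasome, 18 of 32 rose (27 adjusted over the list alone). Proteasome genes had a median of 0.53, but 1 rose after median-ratio scaling, where the median was 0.28 (camera adjusted p = 0.00186, adjusted p = 0.518 with an estimated correlation). Cytosolic heat shock (Hsf1) genes had 1 of 22 rising and 3 falling (0 and 2 adjusted over the list alone) and a median of −0.08, or 0 and 7 with a median of −0.34 after median-ratio scaling (camera adjusted p = 0.0112, adjusted p = 0.518 with an estimated correlation). Sulfur amino acid genes had 5 of 21 rising and 6 falling (7 and 9 adjusted over the list alone) and a median of −0.25, or 3 and 10 with a median of −0.51 after median-ratio scaling (camera adjusted p = 0.0348, adjusted p = 0.226 with an estimated correlation).

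The remaining lists were not called by camera with Hac1 retained. General stress (Msn2/4) genes had 12 of 29 rising and 2 falling (14 and 2 adjusted over the list alone), or 6 and 2 after median-ratio scaling, a median of 0.61 (0.36 after that scaling) and adjusted p = 0.195. Phospholipid and fatty acid synthesis had 5 of 14 rising (5 adjusted over the list alone), or 3 rising and 2 falling after median-ratio scaling, a median of 0.40 and adjusted p = 0.155, and INO1, the inositol-3-phosphate synthase, rose by 3.69 ± 0.22. Ergosterol synthesis had 8 of 23 rising (7 adjusted over the list alone), or 2 rising and 2 falling after median-ratio scaling, a median of 0.37 and adjusted p = 0.432. Glycolysis had 3 of 16 rising (3 adjusted over the list alone), a median of 0.22 that turned to −0.03 after median-ratio scaling, and adjusted p = 0.414. Meiotic genes had 4 of 11 rising and 1 falling (6 and 1 adjusted over the list alone), or 4 and 2 after median-ratio scaling, a median of 0.75 and adjusted p = 0.384, and HOP1, a component of the meiotic chromosome axis, rose by 2.88. Mating genes had 1 of 6 rising (0 adjusted over the list alone), or 0 after median-ratio scaling, a median of 0.62 and adjusted p = 0.492. In UPR signalling HAC1 rose by 2.14 ± 0.16 (limma adjusted p = 3.16e-06) and IRE1, the ER stress sensor that splices HAC1 mRNA, was at 0.35 (adjusted p = 0.2). In that list 1 of 3 was called (1 adjusted over the list alone), with a median of 0.35 and camera adjusted p = 0.392. Of the pair the study chose, HNT1 rose and ODC2, a mitochondrial dicarboxylate carrier, was at −0.33 (adjusted p = 0.195), though 1 of the pair rose and 1 fell after median-ratio scaling. This 1 of 2 (1 adjusted over the list alone) is not independent evidence, since the study chose these genes on these samples, with a median of 0.46 and camera adjusted p = 0.884.

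The same treatment was then examined with Hac1 depleted, in TIR cells with auxin and DTT against auxin alone. KAR2 rose by 1.99 ± 0.12 (limma adjusted p = 5.33e-07), PDI1 by 1.79 and ERO1 by 1.62, while ULI1 was not called (0.40, adjusted p = 0.0721). RTA1, AAD6 and FRE7 rose by 6.02, 4.97 and 4.67, and MNC1, a membrane protein, by 4.74. For ER protein folding 14 of 16 rose (14 adjusted over the list alone). The folding genes here had a median of 0.94, or 0.68 after median-ratio scaling (camera adjusted p = 0.000266, adjusted p = 0.217 with an estimated correlation). Cell wall integrity genes had 18 of 19 rising and 1 falling (18 and 1 adjusted over the list alone) and a median of 2.10 (camera adjusted p = 3.79e-06, adjusted p = 0.544 with an estimated correlation). General stress genes had 24 of 29 rising and 2 falling (24 and 2 adjusted over the list alone) and a median of 1.09 (camera adjusted p = 0.00125, adjusted p = 0.571 with an estimated correlation). Drug efflux genes had 12 of 13 rising (12 adjusted over the list alone) and a median of 1.20 (camera adjusted p = 8.12e-05, adjusted p = 0.412 with an estimated correlation). Cytosolic ribosomal proteins had 128 of 138 falling (130 adjusted over the list alone) and a median of −0.90 (camera adjusted p = 2.00e-43, adjusted p = 0.108 with an estimated correlation), and the electron transport chain 25 of 26 falling (25 adjusted over the list alone) and a median of −1.19 (camera adjusted p = 1.11e-14, adjusted p = 0.412 with an estimated correlation). In all 3372 of 5757 genes were called, 2364 higher and 1008 lower. Median-ratio scaling moved the median of all genes from 0.26 to 0.00 and the calls to 1528 higher and 1567 lower, and turned the medians of ER translocation (from 0.09 to −0.17), cytosolic heat shock (from 0.10 to −0.16) and sulfur amino acid genes (from 0.08 to −0.18). This control group has 2 libraries and that of the retained cells 1, so the counts of the 2 responses are not compared here. The difference of the responses is tested with the additional observations.

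Hac1 depletion under DTT was compared directly, between TIR and no-TIR cells that both received auxin and DTT. ER chaperones such as KAR2 and its cofactor SIL1 were lower in depleted cells, and single genes of iron uptake (ENB1) and drug export (PDR5) were higher. KAR2 was lower by log2 −1.93 ± 0.12 (limma adjusted p = 4.29e-06), at 4051 and 3595 RPKM against 14791 and 14385 RPKM, ULI1 by −5.11 ± 0.18 (adjusted p = 3.73e-08) and YLR349W, a reading frame with no RefSeq entry, by −5.27 ± 0.32 (adjusted p = 4.29e-06). MCD4 was at −2.72 ± 0.13, YET2 at −2.92, DOG1, a sugar phosphatase, at −2.74, and HOP1 at −2.60. IRC4, of unknown function, was at −2.49 and PEX18, of peroxisomal import, at −2.39. Higher in depleted cells were YEL073C, of unknown function (2.52 ± 0.23), and YRO2, a plasma membrane protein (2.35 ± 0.15, adjusted p = 5.03e-06). So were PHO89, a phosphate transporter (2.19 ± 0.24), YAT1, a carnitine acetyltransferase (1.90), and YGP1, a secreted glycoprotein (1.82). Of 5757 genes 350 were called, 216 lower and 134 higher. The count was 125 without the no-TIR auxin and DTT library of 1 h, 136 without the TIR auxin and DTT library of 1 h and 153 in a model without the hour.

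**Figure D2:**
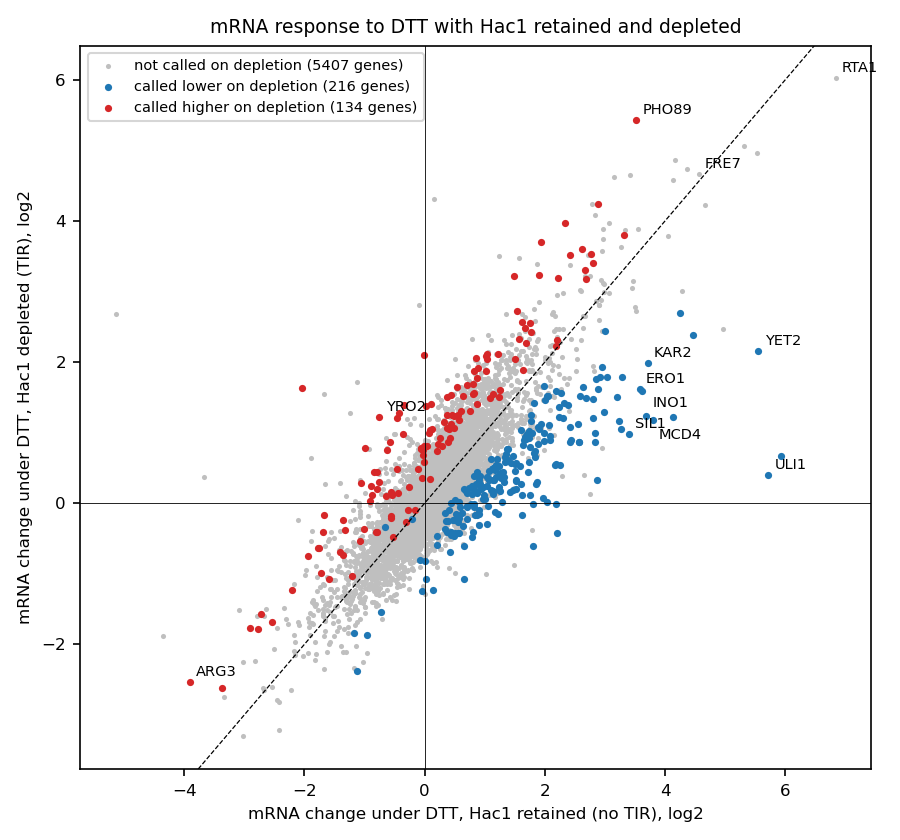
Log2 mRNA change under DTT of each of 5757 genes with Hac1 retained (x axis) and depleted (y axis), with genes called lower on depletion in blue (216), called higher in red (134), the others in grey and a dashed line where the responses are equal. ULI1 (5.72 against 0.40) and KAR2 (3.71 against 1.99) lie below the line, and RTA1 (6.84 against 6.02) was not called on depletion.

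By list, 12 of 16 genes of ER protein folding fell on depletion and 0 rose (13 and 1 adjusted over the list alone). The folding list had a median of −1.05 (camera adjusted p = 6.52e-16, adjusted p = 0.042 with an estimated correlation). Next to KAR2 stood SIL1 (−2.33 ± 0.15), ERO1 (−1.98 ± 0.14), JEM1 (−1.39 ± 0.14) and PDI1 (−0.98 ± 0.14, adjusted p = 0.00147). In N- and O-glycosylation 10 of 36 fell (16 adjusted over the list alone), including PSA1, PMI40 and SEC53 of GDP-mannose synthesis (−1.26 ± 0.13, −1.32 ± 0.15 and −1.17 ± 0.14). The glycosylation list had a median of −0.32 (camera adjusted p = 5.14e-06, adjusted p = 0.464 with an estimated correlation). In ER-Golgi transport 8 of 29 fell (13 adjusted over the list alone), among them ERP2 (−1.23 ± 0.15) and ERV29 (−0.91 ± 0.14). The transport list had a median of −0.29 (camera adjusted p = 4.63e-07, adjusted p = 0.135 with an estimated correlation). ER translocation and signal recognition had 6 of 24 falling (8 adjusted over the list alone) and a median of −0.29 (camera adjusted p = 3.28e-05, adjusted p = 0.638 with an estimated correlation). ER-associated degradation had 3 of 18 falling (4 adjusted over the list alone), among them DER1 (−1.43 ± 0.19) and DFM1 (−0.93 ± 0.13), and a median of −0.15 (camera adjusted p = 0.011, adjusted p = 0.464 with an estimated correlation). GPI anchor synthesis had 2 of 22 falling (2 adjusted over the list alone), 1 of them MCD4, and was not called (median −0.09, camera adjusted p = 0.119). Phospholipid and fatty acid synthesis had 2 of 14 falling, 1 of them INO1 (−2.21 ± 0.18, adjusted p = 2.32e-05), with 3 falling and 1 rising adjusted over the list alone. Its median was 0.01 and its mean −0.15, and camera did not call it (adjusted p = 0.629).

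Higher on depletion were 7 of 18 genes of the iron regulon (9 adjusted over the list alone). The regulon as a whole had a median of 0.37 (camera adjusted p = 1.28e-05, adjusted p = 0.464 with an estimated correlation). ENB1, a siderophore transporter, was at 1.58 ± 0.16 (limma adjusted p = 0.000174) and FRE1, a ferric reductase, at 1.05 ± 0.14. Drug efflux genes had 4 of 13 higher and 1 lower (6 and 1 adjusted over the list alone), including RSB1, a sphingoid base exporter (1.75 ± 0.19), and PDR5 (1.06 ± 0.15). Efflux genes together had a median of 0.29 (camera adjusted p = 0.0244, adjusted p = 0.650 with an estimated correlation). Amino acid synthesis genes had 3 of 27 higher (7 adjusted over the list alone), including ARG3 (1.31 ± 0.14). The amino acid list had a median of 0.27 (camera adjusted p = 7.01e-05, adjusted p = 0.464 with an estimated correlation). General stress genes had 3 of 29 higher, including YGP1 and SPI1 (1.02 ± 0.15), and 1 lower, the glycogen synthase GSY1 (−1.33 ± 0.13), with 7 and 1 adjusted over the list alone and a median of 0.39 (camera adjusted p = 0.00228, adjusted p = 0.741 with an estimated correlation). Cell wall integrity genes had 3 of 19 higher (7 adjusted over the list alone) and a median of 0.45 (camera adjusted p = 7.54e-05, adjusted p = 0.650 with an estimated correlation). Cytosolic heat shock genes had 1 of 22 higher (5 adjusted over the list alone) and a median of 0.20 (camera adjusted p = 0.000805, adjusted p = 0.650 with an estimated correlation). In the TCA cycle LSC2 fell (limma adjusted p = 0.00109) and 1 gene rose (6 rising and 1 falling adjusted over the list alone). The cycle as a whole had a median of 0.49 (camera adjusted p = 0.00215, adjusted p = 0.650 with an estimated correlation). No gene of the electron transport chain, ATP synthase, ribosomal protein, ribosome biogenesis or proteasome lists was called by limma. Of these camera called the electron transport chain (median 0.18, adjusted p = 0.0236, adjusted p = 0.856 with an estimated correlation) and ATP synthase (median 0.25, adjusted p = 0.0168, adjusted p = 0.725 with an estimated correlation), both higher. In all camera called 14 of the 29 lists for mRNA on depletion, and 1 with an estimated correlation.

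On depletion KAR2 footprints were lower by −2.22 ± 0.11 (limma adjusted p = 3.37e-05), ULI1 by −7.35 ± 0.18 (adjusted p = 4.95e-07), INO1 by −3.58 ± 0.17 and ERO1 by −2.29 ± 0.11. YRO2, ENB1, YAT1 and CRC1, a mitochondrial carnitine carrier, were higher by 2.45 ± 0.20, 2.02 ± 0.23, 2.12 and 1.90. For ER protein folding 12 of 16 fell (12 adjusted over the list alone), with a median of −1.16 (camera adjusted p = 1.08e-16, adjusted p = 0.160 with an estimated correlation). Glycosylation had 16 of 36 falling (20 adjusted over the list alone) and ER-Golgi transport 16 of 29 (22 adjusted over the list alone), with medians of −0.34 and −0.43 (camera adjusted p = 1.04e-12 and 1.1e-11, adjusted p = 0.160 with an estimated correlation for both). In all camera called 18 of the 29 lists for footprints on depletion, and 0 with an estimated correlation. The iron regulon had 8 of 17 rising (9 rising and 1 falling adjusted over the list alone) and a median of 0.34 (camera adjusted p = 0.000317, adjusted p = 0.160 with an estimated correlation). Of 5338 genes 513 were called, 309 lower and 204 higher. The count was 126 and 193 without the no-TIR auxin and DTT libraries of 1 h and 2 h. It was 204 and 234 without the TIR auxin and DTT libraries of 1 h and 2 h, 201 without the hour in the model, and 946 when only the 8 DTT libraries were fitted.

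The retained response and the depletion comparison share the no-TIR auxin and DTT libraries. Of the 1647 genes that rose with Hac1 retained, 181 were among the 216 lower on depletion, where independent lists would share 61.8. Simulations without an effect of depletion gave a median of 0 and at most 3. They leave almost no gene to be called on depletion, so they cannot gauge how many of the 181 came from the shared libraries. Part of the excess may come from the shared libraries. A comparison without shared libraries, auxin against vehicle under DTT within TIR cells, called 345 genes, 230 lower and 115 higher, and KAR2 was lower by −1.82 (limma adjusted p = 6.99e-06). Of the 230, 177 had risen with Hac1 retained, against 65.8 for independent lists, and of the 115 higher genes 29 had fallen, against 13.8. That count of 345 was 93 and 216 without the TIR vehicle and DTT libraries of 1 h and 2 h, 108 without the TIR auxin and DTT library of 1 h and 137 without the hour in the model. In no-TIR cells, auxin against vehicle under DTT gave 0 calls by limma. There 91 of 5757 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that no effect would give. So the test may have been conservative for this comparison, and 0 calls do not exclude small effects of auxin. There camera called 11 of the 29 lists with 0 members called and no depletion of Hac1, and 0 with an estimated correlation, so list calls with the preset correlation are not specific to depletion. It placed ribosome biogenesis higher (median 0.17, adjusted p = 9.16e-15, adjusted p = 0.796 with an estimated correlation) and general stress genes lower (median −0.22, adjusted p = 4.29e-08, adjusted p = 0.796 with an estimated correlation).

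Ribosome footprints were next compared with mRNA for the DTT response with Hac1 retained. Footprints of KAR2 rose by 3.73 and those of HAC1 by 3.86 ± 0.15 (limma adjusted p = 1.96e-06), the latter with a rise in TE of 1.71 ± 0.19 (adjusted p = 2.35e-05). Footprints of ER protein folding genes rose for 14 of 16 (14 adjusted over the list alone), with a median of 2.15, or 1.81 after median-ratio scaling (camera adjusted p = 9.69e-06, adjusted p = 0.360 with an estimated correlation). Proteasome footprints rose for 31 of 32 (31 adjusted over the list alone), or 18 after median-ratio scaling, with a median of 0.70 (camera adjusted p = 4.77e-05, adjusted p = 0.415 with an estimated correlation), and ribosomal protein footprints fell for 132 of 136 (132 falling and 1 rising adjusted over the list alone), with a median of −0.86 (camera adjusted p = 3.83e-47, adjusted p = 0.319 with an estimated correlation). Of 5338 genes 3319 were called for footprints, 2537 higher and 782 lower. Median-ratio scaling moved the median of all genes from 0.34 to 0.00 and the calls to 1414 higher and 1424 lower. With Hac1 depleted, 3707 were called for footprints, 2649 higher and 1058 lower, and the scaling moved their median from 0.29 to −0.02 and the calls to 1671 higher and 1778 lower.

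TE changed for 201 of 5329 genes with Hac1 retained, 123 higher and 78 lower. DFP3, of unknown function, rose by 2.41 ± 0.22 (limma adjusted p = 4.75e-06) and NFT1, a putative transporter, by 2.19 ± 0.22. RPL22B of the large ribosomal subunit fell by 3.21 ± 0.29 on the log2 scale and HPF1, a cell wall glycoprotein, by 2.85 ± 0.28. With Hac1 depleted TE was called for 1126 genes, 766 higher and 360 lower, with GTT2, a glutathione transferase, at 3.29 and CTS1, the chitinase, at −2.83. That count was 554 and 329 without the TIR auxin libraries of 1 h and 2 h and 189 without the TIR auxin and DTT library of 1 h. No list but the proteasome was called there, with 10 of 32 rising (15 adjusted over the list alone) and a median of 0.32 (camera adjusted p = 0.0208, adjusted p = 0.993 with an estimated correlation). With Hac1 retained, camera called cytosolic ribosomal proteins (4 of 136 fell, 4 adjusted over the list alone, median −0.06, adjusted p = 0.000406, adjusted p = 0.888 with an estimated correlation) and sulfur amino acid genes (3 of 21 fell, 5 falling and 2 rising adjusted over the list alone, median −0.14, adjusted p = 0.00915, adjusted p = 0.580 with an estimated correlation). On depletion 19 genes were called for TE, 12 higher and 7 lower. Camera called 7 lists there, and 0 with an estimated correlation (adjusted p = 0.797 for each). Higher were the mitochondrial ribosome (median 0.25, camera adjusted p = 1.43e-08), cytosolic ribosomal proteins (0.18, 1.91e-06), respiratory chain assembly and coenzyme Q (0.16, 0.0114), the proteasome (0.16, 0.0137) and the pair the study chose on these samples (0.98, 0.0114). Lower were glycosylation (−0.17, 0.0311) and cell wall integrity genes (−0.26, 0.0137). ULI1 was at −2.24 ± 0.13 (adjusted p = 2.03e-08), ADH4, an alcohol dehydrogenase, at −1.54 and MLO1, of mitochondrial location, at −1.36. YOL038C-A, a short reading frame, was at 2.16. The count of 19 was 11 and 221 without the no-TIR auxin and DTT libraries of 1 h and 2 h, and 12 and 29 without the TIR auxin and DTT libraries of 1 h and 2 h.

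The study asked whether Hac1 drives longer transcripts that are poorly translated, which would appear per gene as mRNA up with TE down. With Hac1 retained, 29 genes had mRNA called higher and TE called lower under DTT. Simulations without any effect gave a median of 0 and at most 1. Those held no rise of mRNA, so they do not gauge the noise that mRNA and TE share among genes that rose. With the measured changes under DTT kept, simulations gave a median of 41 and at most 63. These keep the measured TE falls too, so neither kind of simulation tests the count of 29 genes. In order of the TE change the leading genes with calls that held in every setting were IRC4 (YDR540C; mRNA 3.27 ± 0.27, TE −2.98 ± 0.33, limma adjusted p = 2.99e-05) and HEM15 (YOR176W), the ferrochelatase of heme synthesis (mRNA 3.24 ± 0.21, TE −2.53 ± 0.18, adjusted p = 4.85e-07). Next came HNT1 (YDL125C), a nucleotide-binding hydrolase (mRNA 1.25 ± 0.24, TE −1.73 ± 0.23, adjusted p = 0.000218), DMA2, a ubiquitin ligase (mRNA 1.81, TE −1.69), and RTA1 (mRNA 6.84, TE −1.56). Footprints of the 29 were called higher for 10, lower for 4 and not called for 15. The 4 lower were HNT1, YBL008W-A, SUL2, a sulfate permease, and YGR011W, the last chosen after its values were seen. SUL2 left the list without the no-TIR auxin and DTT library of 1 h (mRNA adjusted p = 0.118, TE adjusted p = 0.121) or of 2 h (0.1 and 0.0683), and its mRNA call was lost with median-ratio scaling (adjusted p = 0.16), with a mean of at least 20 RPKM (0.056) and without the hour (0.0617). YBL008W-A left it without the library of 1 h (mRNA adjusted p = 0.0821, TE adjusted p = 0.101). HNT1 footprints were 1551 RPKM with auxin alone and 1122 and 1073 RPKM with auxin and DTT (−0.48 ± 0.14, adjusted p = 0.0192), and that call was lost without the no-TIR auxin and DTT library of 1 h (adjusted p = 0.076) or of 2 h (adjusted p = 0.0614).

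On Hac1 depletion, TE was called higher for 5 of the 29 genes, and mRNA lower for 9. With Hac1 depleted, TE was still called lower under DTT for 10 of the 29, among them FRE3, a siderophore reductase (−2.76; its call with Hac1 retained was lost without the hour, adjusted p = 0.0702), and HEM15 (−1.04, limma adjusted p = 0.000155), which is also 1 of the 5. TE was higher for IRC4 (3.03 ± 0.26, limma adjusted p = 4e-06), HNT1 (1.70 ± 0.18, adjusted p = 3.7e-05), DMA2 (1.60 ± 0.14), HEM15 (1.52 ± 0.14) and ASA1, a subunit of a chaperone-regulating complex chosen after its values were seen (1.06). HNT1 footprints were 2042 and 2148 RPKM in depleted cells (0.93 ± 0.11, adjusted p = 0.00215). Its mRNA was lower (−0.76 ± 0.19, adjusted p = 0.034), a call lost without the no-TIR or the TIR auxin and DTT library of 1 h (adjusted p = 0.367 and 0.4) and without the hour (adjusted p = 0.168). Independent lists would share 0.07 and 1.08 genes. The 29 were chosen among risen genes, and of all 1647 such genes 181 were lower on depletion. So 1.08 is too low a reference for the mRNA count. Simulations with the DTT effect kept and no effect of depletion gave a median of 0 and at most 1 for either count. They leave almost no gene to be called on depletion, so they cannot gauge what shared libraries add. The comparisons share libraries, and part of the excess may come from them. Between auxin and vehicle within TIR cells, which shares none, mRNA of 10 of the 29 was lower and of 0 higher by limma, against 1.17 for independent lists. Of all 1647 risen genes 177 were lower in that comparison, so 1.17 is too low a reference as well.

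In the deletion experiment, with 1 library per group and so no test, KAR2 mRNA in WT rose from 1440 RPKM to 13673 RPKM with DTT and 13189 RPKM with Tm, and in hac1 deletion cells it was 907, 1277 and 1023 RPKM. The largest rises in WT under both drugs (log2, DTT then Tm) were those of YET2 (5.75 and 5.41), ULI1 (6.01 and 4.67), GIP1, a meiosis-specific phosphatase subunit (4.44 and 4.87), HOP1 (4.42 and 4.20), AMS1, the vacuolar mannosidase (5.35 and 4.17), and PEX18 (4.57 and 4.15). In the deletion these were 1.53 and 0.15 for YET2, −0.12 and −0.21 for ULI1, −0.37 and 0.04 for GIP1, −0.63 and −0.22 for HOP1 and 2.68 and 0.01 for AMS1. PEX18 stood at 1.58 with DTT. MNC1, a membrane protein, rose in both strains (4.77 and 4.04 in WT, 4.92 and 1.57 in the deletion). Large falls in WT were those of PHO3, an acid phosphatase (−2.98 and −2.79), MRH1, a membrane protein (−2.34 and −2.32), NCE102, of eisosomes (−2.94 and −2.26), and CHA1, a serine deaminase (−3.16 and −2.17). With DTT they fell in the deletion as well, at −2.58, −1.78, −2.94 and −4.50.

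By the fixed rule, 628 of 5622 genes in WT changed at least 2-fold in the same direction under both drugs, 496 higher and 132 lower, against 7.0 at the median and at most 13 in simulations of unchanged libraries. Of 5566 genes in the deletion, 14 did, 12 higher and 2 lower, against a simulated 7.0 and at most 13. Independent lists from each drug would share 100.6 and 14.1 genes in WT and 1.9 and 0.4 in the deletion, and part of the excess may come from the shared untreated library. For footprints the counts were 632 of 5260 in WT and 25 of 5147 in the deletion. The strains shared 5 of the genes higher in mRNA and 0 of those lower. The shared genes, all but MNC1 chosen after their values were seen, were MNC1, HSP42, a small heat shock protein, DIA1, RCN2, a calcineurin regulator, and YPR096C. Single drugs differed in the deletion, where 518 genes were at least 2-fold higher and 275 lower with DTT, against 20 and 8 with Tm. In WT, 1040 were higher and 388 lower with DTT, and 544 and 205 with Tm. Median-ratio scaling changed the WT split of 496 higher and 132 lower to 344 and 246, since the median of all genes was 0.30 with DTT and 0.15 with Tm.

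**Figure D3:**
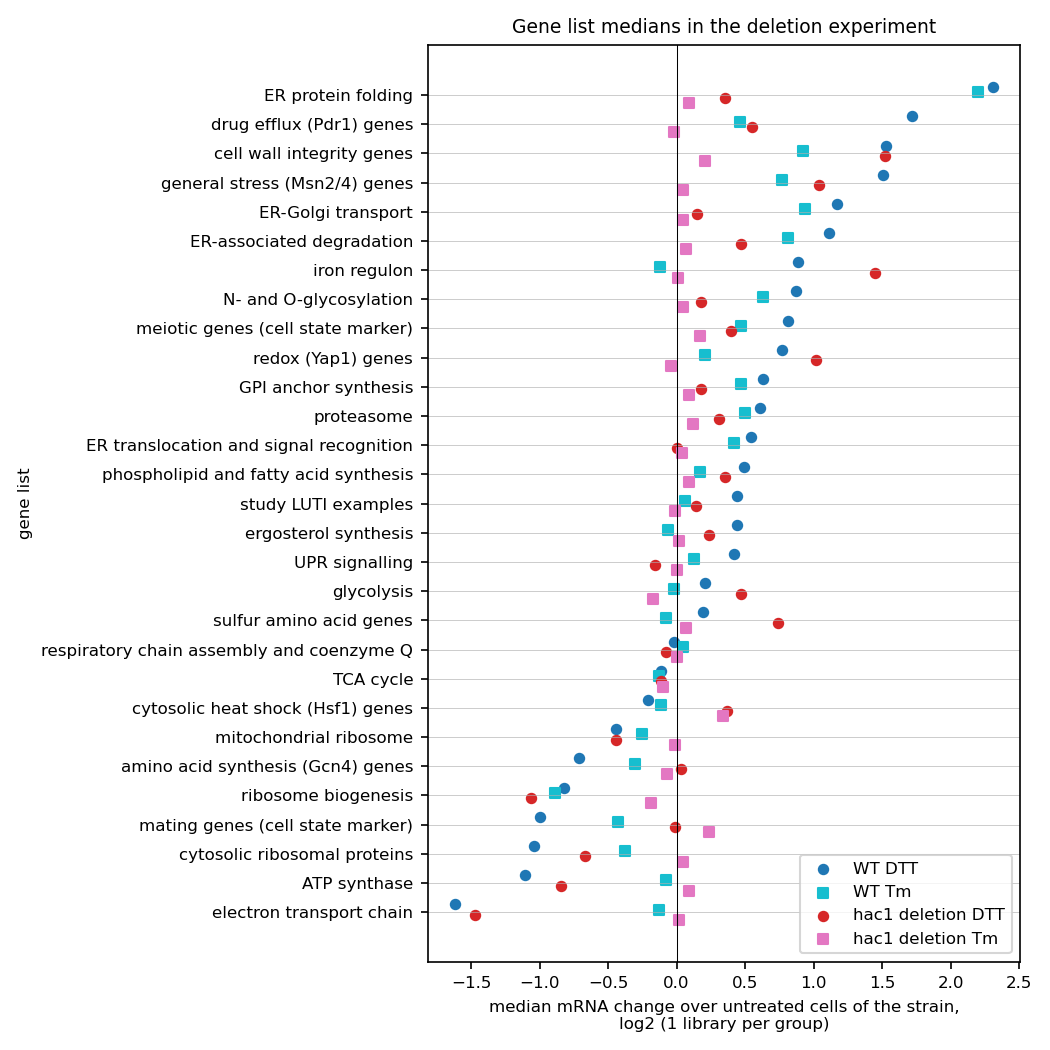
Median log2 mRNA change of each of the 29 lists against the strain's own untreated library, with WT in blue (DTT) and cyan (Tm), hac1 deletion in red (DTT) and pink (Tm), and 1 library behind each group. ER protein folding lies at 2.31 and 2.20 in WT and at 0.35 and 0.09 in the deletion, and the electron transport chain at −1.62 and −0.13 in WT and at −1.47 and 0.02 in the deletion.

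The ER protein folding list had a median of 2.31 with DTT and 2.20 with Tm in WT, each higher than the random lists, with 12 of 16 members at least 2-fold higher under each drug. In the deletion the medians were 0.35 and 0.09 (percentiles 95.92 and 86.74). ER-Golgi transport stood at 1.17 and 0.94 in WT against 0.15 and 0.05, ER-associated degradation at 1.11 and 0.81 against 0.47 and 0.07, and glycosylation at 0.87 and 0.63 against 0.18 and 0.05. Other lists moved with DTT in both strains. Cell wall integrity genes had medians of 1.53 in WT and 1.52 in the deletion with DTT and of 0.92 and 0.21 with Tm. The electron transport chain had −1.62 and −1.47 with DTT (percentile 0.0 in both) and −0.13 and 0.02 with Tm. General stress genes had 1.51 and 1.04 with DTT and 0.77 and 0.05 with Tm, and the iron regulon 0.89 and 1.45 with DTT and −0.12 and 0.01 with Tm. Ribosomal protein genes had −1.04 and −0.67 with DTT and −0.38 and 0.05 with Tm. Cytosolic heat shock genes had −0.21 and −0.11 in WT but 0.37 and 0.34 in the deletion.

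The strains of the deletion experiment differed before treatment in more than HAC1. Across all 3 treatments 122 of 5664 genes were at least 2-fold lower in the deletion and 54 at least 2-fold higher, with no replicate check. Mating genes had a median of −4.76 in untreated cells, with 8 of 8 members at least 2-fold lower. STE2, the receptor of α-factor, was at 936.0 RPKM in untreated WT and 27.9 RPKM in the deletion, and MFA2, a precursor of a-factor, at 1017.7 and 10.5 RPKM. These markers were chosen after their values were seen. They were also low in the strains of the auxin experiment, where STE2 reached 13.5 to 26.9 RPKM in mRNA libraries and MFA2 at most 5.8 RPKM. Amino acid synthesis genes had a median of −1.61 in untreated cells, with 19 of 27 at least 2-fold lower, and proteasome genes one of 0.93, with 8 of 32 higher. YHB1 was higher in the deletion by 2.24 untreated, 2.08 with DTT and 3.99 with Tm. Genes of whole chromosomes were also shifted. Against the other 14 chromosomes, the median mRNA ratio of chromosome II was higher by 0.53 to 0.58 over the treatments, with footprints at 0.47 to 0.57. Chromosome VIII was lower in every treatment, with footprints at −0.98 to −0.95. Ratios of treated to untreated cells of the same strain, used for all counts of response above, cancel a shift that is constant over the treatments. They do not cancel the effect of the starting level, since a gene already low in the deletion has little room to fall there. STE2 mRNA fell in WT to 227.8 RPKM with DTT and 372.0 RPKM with Tm, and in the deletion was 32.7 RPKM with each. So counts of genes that fell are not free of the difference between the strains.

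**Figure D4:**
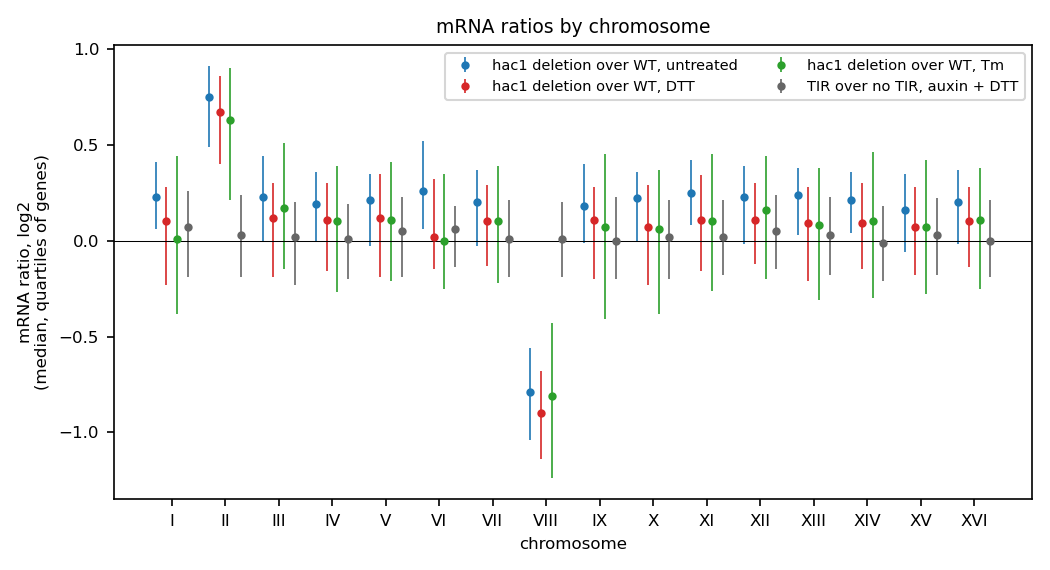
Median log2 mRNA ratio of the genes of each chromosome, with bars from the lower to the upper quartile of genes, for hac1 deletion over WT untreated (blue), with DTT (red) and with Tm (green) and for TIR over no-TIR cells with auxin and DTT (grey). Untreated medians were 0.75 on chromosome II and −0.79 on chromosome VIII and 0.16 to 0.26 on the others.

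The genes found by depletion were finally examined in the deletion experiment, which shares no library with it. Of 214 genes lower on depletion and measured in both, 136 were at least 2-fold higher in WT under both drugs, against 18.8 for independent lists. Their median change was 1.51 with DTT and 1.46 with Tm in WT, and 0.18 and 0.04 in the deletion. The 128 genes higher on depletion had medians of 0.39 and −0.22 in WT and of 0.84 and 0.02 in the deletion. Of these, 17 were lower in WT under both drugs, against 2.9 for independent lists, while 17 were higher, against 11.3. The rule for mRNA up with TE down gave 36 of 5374 genes in WT and 5 of 5382 in the deletion. Simulations of unchanged libraries, which hold no rise of mRNA either, gave medians of 7.0 in each and at most 13 and 14. The strains shared 2 genes. With footprint RPKM of at least 10 in every library, a setting chosen after seeing the data, 15 and 2 remained in number. Independent lists would share 0.11 genes with the auxin list, which is too low a reference, since both lists require a rise of mRNA. Of the 28 genes of the auxin list measured here, 8 were among the 36. They were IRC4 (TE −2.14 with DTT and −2.65 with Tm in WT, 0.28 with DTT in the deletion), HEM15 (−1.55 and −1.68, then −0.63), RTA1 (−0.86 and −1.35, then −2.24) and MIG3, a glucose-linked repressor (−1.11 and −0.60, then 0.51). The TE call of MIG3 in the auxin experiment was lost without the no-TIR auxin and DTT library of 1 h (adjusted p = 0.0863) and without the hour (adjusted p = 0.0549). The other 4 were chosen after their values were seen: NCR1, a sterol transporter (−1.86 and −2.24, then −0.09), YPL247C (−1.29 and −0.97, then −0.28), GSY1 (−0.74 and −0.71, then 0.27) and ASA1 (−0.72 and −0.68, then 0.12). HNT1 was outside the list because its mRNA rose by 1.52 with DTT and 0.53 with Tm. Its TE was at −1.71 with DTT and −0.72 with Tm in WT and 0.19 and −0.04 in the deletion. Of the 10 largest TE falls of the auxin list, those of DMA2 (0.28 and −0.12) and YBL008W-A (0.97 and 1.3) did not recur in WT. Also outside were FRE3 (−1.35 and −0.74), YLR460C (−2.01 and −0.92) and SUL2 (−0.38 and −0.46), whose TE was lower in WT.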

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

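The test of a response to DTT without Hac1 as the whole cause was chosen after the result was seen, and the other tests in this part before. Differences between the strains in their response to the same treatment were tested as interaction terms, and each of the 3 tests called genes.

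The response of mRNA to DTT differed between TIR and no-TIR cells with auxin for 61 genes by limma, 53 with a smaller or more negative change in depleted cells and 8 with a larger one. ULI1 led (−5.32 ± 0.29, adjusted p = 4.78e-06), with MCD4 (−2.62 ± 0.21), YET2 (−3.39 ± 0.34) and DOG1 (−2.91 ± 0.27) on the same side and YRO2 (1.97 ± 0.25) on the other. Of ER protein folding genes 8 of 16 were called lower (13 adjusted over the list alone), with a median of −1.07 (camera adjusted p = 5.71e-15, adjusted p = 0.0473 with an estimated correlation). Glycosylation had 4 of 36 (9 adjusted over the list alone) and a median of −0.46 (camera adjusted p = 2.91e-07, adjusted p = 0.350 with an estimated correlation). Camera called 15 lists in all, and 1 with an estimated correlation. The count was 22 without the no-TIR auxin and DTT library of 1 h, 256 and 37 without the TIR auxin libraries of 1 h and 2 h, 37 and 33 without the TIR auxin and DTT libraries of 1 h and 2 h, and 20 without the hour in the model.

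Footprints differed in the same test for 133 genes, 96 lower and 37 higher. ULI1 (−5.72 ± 0.30, limma adjusted p = 0.000152), INO1 (−3.85 ± 0.28) and YET2 (−3.62 ± 0.35) were lower. CIS1 (YLR346C; 2.87 ± 0.48) and YRO2 (2.00 ± 0.32) were higher. ER protein folding had 11 of 16 lower (12 adjusted over the list alone) and a median of −1.14 (camera adjusted p = 1.62e-13, adjusted p = 0.212 with an estimated correlation), among 21 lists called, of which 0 were called with that correlation. The count was 20 and 46 without the no-TIR auxin and DTT libraries of 1 h and 2 h, 943 without the TIR auxin library of 1 h, 58 and 27 without the TIR auxin and DTT libraries of 1 h and 2 h, 27 without the hour in the model and 16 when only the groups compared were fitted.

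The effect of auxin against vehicle under DTT differed between the strains for 53 genes, 43 lower in TIR cells and 10 higher. They include ULI1 (−4.55 ± 0.25, limma adjusted p = 6.31e-06), MCD4 (−2.38 ± 0.19), YET2 (−2.74 ± 0.30) and IRC4 (−2.22 ± 0.31), and on the other side PHO89 (2.21 ± 0.34), YRO2 (1.76 ± 0.22) and PHO84, a phosphate transporter (1.36 ± 0.19). The count was 24 and 30 without the no-TIR vehicle and DTT libraries of 1 h and 2 h, 29 without the no-TIR auxin and DTT library of 1 h, 22 without the TIR vehicle and DTT library of 1 h, 30 and 31 without the TIR auxin and DTT libraries of 1 h and 2 h, 18 without the hour in the model and 33 without the filter on low values.

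ER protein folding genes still rose under DTT in depleted cells, where 14 of 16 were called. Whether a response to DTT that needs no Hac1 could be the whole cause stays open. Relative to all genes, the list rose by a median of 0.51 more in depleted cells than in hac1 deletion cells, just past the bound of 0.5, but members ranged from −0.30 to 1.39 (quartiles 0.21 to 0.92) and 1 deletion library with DTT stands behind them. Incomplete depletion may contribute and stays open: 77 genes that rose in WT under both drugs and stayed within 0.25 in the deletion had a median 0.14 above that of all genes in depleted cells (0.40 against 0.26, quartiles 0.24 to 0.68). The strains of the 2 experiments also differ. No treatment time was recorded here for the deletion libraries, against 1 h and 2 h for the depleted cells. These libraries cannot separate strain or time from the depletion.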

How the results depend on the processing

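The settings with footprint RPKM of at least 10 and with chromosomes II and VIII left out were chosen after seeing the data, and the others before. Of 168 counts under other settings 118 stayed within 1.5 times the reported count, and so did 27 of 60 counts without 1 library. Of 2655 values of named genes under other settings 2443 kept direction and side of the threshold, 164 lost the call, 48 gained one and 0 reversed, and 124 of 178 called results kept the call throughout. The cause of the changes below was not tested, except that other folds and minimum values change how many genes can pass.

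Without the hour in the model (no replicate block) the counts were 153 for mRNA on depletion, 201 for footprints on depletion, 137 for auxin against vehicle in TIR cells, 18 for the difference in the auxin effect, and 20 (mRNA) and 27 (footprints) for the difference in the DTT response. The block rests on the labelled hour. Differences between the hours correlated between groups at −0.09 to 0.61 for mRNA (over 0.1 in 8 of 10 pairs of groups) and at 0.02 to 0.77 for footprints (6 of 10), so not every pair of groups shared them. Leaving the hour out moved no other count by over 1.5 times.

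Fitting only the 8 DTT libraries gave 946 for footprints on depletion, and only the groups compared gave 16 for the footprint difference in the DTT response. No filter on low values gave 33 for the auxin effect difference and 31 for the mRNA difference in the DTT response. With footprint density called lower in place of TE, 4 genes had mRNA up. In the deletion experiment, 1.5-fold and 3-fold gave 1523 and 207 for WT mRNA, 1463 and 231 for WT footprints, 76 and 4 for hac1 deletion mRNA and 94 and 4 for its footprints. Minimum RPKM 3 gave 41 and 42 for the latter strain, and pseudocount 5 gave 15 for its footprints. The rule for mRNA up with TE down gave, in WT, 55 at minimum RPKM 3, 22 at 30, 68 at 1.3-fold, 14 at 2-fold and 15 with footprint RPKM of at least 10. In the deletion it gave 10 at minimum RPKM 3, 16 at 1.3-fold, 1 at 2-fold and 2 with footprint RPKM of at least 10.

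Without 1 library the counts ranged from 125 to 331 for mRNA on depletion, 126 to 234 for footprints on depletion, 189 to 1432 for TE with Hac1 depleted and 11 to 221 for TE on depletion. They ranged from 93 to 266 for auxin against vehicle in TIR cells, 0 to 3 in no-TIR cells, 22 to 62 for the auxin effect difference, and 22 to 256 (mRNA) and 20 to 943 (footprints) for the DTT response difference. A lone library in a group is then assumed to vary like the others.

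Lists called by camera fell with an estimated correlation to 1 for mRNA on depletion, 1 for the mRNA difference in the DTT response, and 0 for mRNA, footprints and TE with Hac1 retained or depleted, for footprints and TE on depletion, for auxin in no-TIR cells and for the footprint difference. With fry the lists called were 7 (mRNA), 9 (footprints) and 0 (TE) on depletion, 24 for footprints with Hac1 depleted, 0 for auxin in no-TIR cells, and 4 (mRNA) and 5 (footprints) for the difference. The planned count-based tests were not run because neither table holds counts. A fit without the only no-TIR auxin library could not be made. Neither could a fit of the retained response from its own groups alone with the hour in the model. That fit was not tried without the hour. Depth left 712 to 1010 genes at 0 in the auxin footprint libraries and 482 to 621 in the auxin mRNA libraries.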

Other observations

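The tests of the authors' normalization and of mislabelled libraries were chosen after the results were seen, and the other tests in this part before. In hac1 deletion cells, the few genes that rose under both drugs include chaperones of the cytosol. BTN2, a factor that sorts misfolded protein, rose by 1.93 with DTT and 1.91 with Tm, and HSP42, a small heat shock protein, by 2.52 and 1.39. HSP42 mRNA also rose at least 2-fold under both drugs in WT, so its rise is not particular to the deletion. Footprints of HSP82, the Hsp90 chaperone, rose by 1.07 and 1.02, just past the 2-fold rule. These genes were chosen after their values were seen, and 1 library stands behind each group. The cytosolic heat shock list had medians of 0.37 and 0.34 in the deletion and of −0.21 and −0.11 in WT. For mRNA 14 genes changed under both drugs in the deletion, only just above the most that simulations of unchanged libraries reached (13, with a median of 7.0). For footprints 25 genes did, where the simulations had a median of 5.0 and reached at most 11.

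The hac1 deletion strain differed from WT before treatment in mating genes, in amino acid synthesis genes and along chromosomes II and VIII. The authors' normalization is argued against, since 1 factor per library moves every chromosome alike and the 16 chromosome medians spanned 1.54 in untreated mRNA. A mislabelled mRNA library is argued against by HAC1 mRNA, which reached at most 1.77% of the WT level in the deletion. A mislabelled footprint library is argued against by the a- and haploid-specific genes, whose footprints had a median of at most 5.01% of WT in the deletion (upper quartile at most 7.97%), and by chromosome VIII (−0.98 to −0.95), although HAC1 footprints, low in untreated WT, reached 30.5% there. Another chromosome content and mating state of the strain may be the source but stays open, since only part of the prediction held. Of 48 medians of segments of these chromosomes, 48 differed from the other 14 chromosomes by over 0.3 in the predicted direction. No-TIR cells with vehicle and DTT, set against WT with DTT, showed no such shift in mRNA (0.0 on chromosome II and 0.01 on VIII). But only 12 of 14 a- and haploid-specific mRNAs were low enough in all 3 treatments. SAG1, an α-specific gene, reached 40.4 RPKM, above the bound of 20. That bound cannot tell the strains apart, since SAG1 mRNA was at 15.1 to 33.0 RPKM in WT.

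Genes with mRNA up and TE down were weighed as noise and as an effect of Hac1. Noise in mRNA values, which enter both the change and the ratio, is argued against for the genes as a set by the deletion experiment. There 28 of the genes had a median TE change of −0.55 in WT with DTT. Of 10000 random sets of other risen genes 0.0% were as low. The sets were not matched on expression or on the size of the rise. Single genes went both ways, with IRC4 and HEM15 at −2.14 and −1.55 and DMA2 and YBL008W-A at 0.28 and 0.97. Dependence on Hac1 may explain part of the pattern but stays open. The TE change with DTT was higher by a median of 0.23 in the deletion than in WT (random sets −0.06). That lies between the bounds of 0.1 and 0.3 set for no dependence and for dependence. With Tm, for which no bound was set, it was higher by 0.43 (random sets 0.09). For either drug 0.0% of random sets were as high. Against full dependence, their TE also fell with DTT within the deletion (median −0.22, random sets 0.05, 0.0% as low), though not with Tm (0.17). Values per gene cannot show which transcript isoform the reads came from, so longer isoforms were not tested.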
